A study of Mus musculus with 6 samples.

How the data were processed

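Single-cell RNA sequencing was run on cells from mouse blood that lacked lineage markers and carried Thy1, a sort that enriches for innate lymphoid cells (ILCs); the labels do not list the lineage markers. There were 6 libraries from 4 strains: 3 wild-type (WT) libraries and 1 library each of Nude mice, of a strain labelled dKO and of a strain labelled Id1. The labels do not spell out dKO, and it is used here only as a name. Nude mice lack a normal thymus. Nothing in the labels says that the 3 WT libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. The Nude, dKO and Id1 strains have no replicate, and each was assumed to vary as the WT libraries do.

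The deposited files hold raw UMI counts per gene and cell barcode, 1 matrix per library, made by the authors with software version 3.1.0 in matrix format version 2, per the file headers. Cell Ranger, Seurat and the genome build mm10 are named in the submitters' processing notes. The annotation release and the settings used to call cells are not given in the sources used here. All 6 matrices list the same 31053 features, and together they hold 21649 barcodes and 104621953 UMIs. Gene symbols and identifiers were taken from the files. Positions were taken from GENCODE vM21 on GRCm38 (mm10), which may differ from the annotation the authors used, and were found for 99.9% of the 13290 genes tested in all retained cells.

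Cells with under 500 detected genes or over 10% mitochondrial UMIs were left out (432 cells, 2% of barcodes). Scrublet was run per library as part of scanpy 1.11.5, and the cells above its own threshold were left out as well. That threshold marked only 52 of 21649 barcodes (0.24%), so doublets must be taken as mostly still present; an alternative left out the 778 barcodes with the highest scores, 0.8% of a library's cells per 1000 cells. The remaining 21165 cells were scaled to 10000 counts and log-transformed. Of these values, 2000 variable genes without T cell receptor and CD3 genes gave 30 principal components, 15 nearest neighbours and Leiden clusters at resolution 1, with no correction between libraries (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9, matplotlib 3.10.9).

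Clusters were named from 16 marker lists. A cluster took the name of a list, as "X-like", when at least 3 of its markers and at least 40% of the list were raised by a log2 fold over 1 and detected in over 10% of the cluster's cells, with no more markers of another list among the 10 leading genes, and with Cd3d in at most 50% of cells for a name other than T cell. The marker lists were written before the data were examined, but these thresholds were set after the clusters had been seen, so the shares of the clusters they keep out are given in the report. Clusters with at least 2 of Rag1, Ptcra, Dntt and Arpp21 raised were noted as carrying thymocyte genes. Names rebuilt in this way may differ from those of the study.

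UMIs were summed per library over all retained cells, over ILC2-like cells and over cluster 4, the only cluster with at least 20 cells in each of the 6 libraries (no named class had as many). Sums of fewer than 20 cells were not used, which left WT replicate 1 with its 5 ILC2-like cells out of the ILC2-like comparison. Each set of sums was tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): filterByExpr, TMM scaling, quasi-likelihood fit and test, Benjamini-Hochberg threshold of 0.05. All libraries entered 1 fit, which also tested dKO against Id1 directly. The fit had 1 residual degree of freedom in ILC2-like cells, and 2 in all retained cells and in cluster 4. In ILC2-like cells the prior degrees of freedom were infinite, so each gene was tested against the spread fitted over all genes. A gene's own difference between the WT libraries thus hardly entered its p-value there. The prior degrees of freedom were 2.34 in all retained cells and 15.97 in cluster 4. Each SE is the log2 fold change divided by the square root of the F statistic. Every adjusted p below is from this test unless another tool is named. Levels are given as CPM, with library sizes scaled by TMM. Where no cell was counted, 3 counts of the total are given as the limit, somewhat below the upper bound of the exact interval; it limits cells with a UMI, not cells that express the gene. A gene with 0 UMIs on one side is given as a bound against a floor of 3 counts over the group. With 1 to 3 UMIs the ratio of CPM is given with an exact 95% interval, which covers counting error only.

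In all, 24 gene lists were fixed for ILC2 identity, ILC precursors, ILC3 and type 17 genes, NK and cytotoxic genes, the T cell receptor complex, thymocyte genes, naive lymphocyte genes, trafficking receptors, E and Id proteins, activation, immediate early and stress genes, interferon response, cell cycle, MHC class II, MHC class I, glycolysis, ribosomal proteins, mitochondrially encoded genes, and markers of B cells, myeloid cells, neutrophils, erythroid cells, platelets and basophils. Lists with at least 4 tested members were tested with camera, which compares a list with all other genes, at a correlation between genes preset to 0.01. With the correlation estimated from these few libraries, no list passed in any comparison. That version had only the 1 or 2 residual degrees of freedom of the fit, so hardly any list could pass it. Its p-values are given beside each call and do not decide whether a list moved. The fry test, which asks whether a list's own genes move on balance one way, was run as well. Shares of cells were tested with edgeR on cells per class and library, and each share has an exact Clopper-Pearson 95% interval. For shares of cells with at least 1 UMI of a gene, cells were thinned to 1000 UMIs, and 337 cells with fewer were left out.

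The genes named in the text follow a rule: Tcf3, Tcf12, Id1 and Foxn1; for each list up to 4 members with the largest change among those past the threshold, or the 2 with the smallest p as values; and the 10 largest rises and 10 largest falls past the threshold, with a value outside all WT libraries and a CPM of at least 50 in the higher group (5 and 5 in cluster 4; the 5 smallest p where none passed). Receptor and immunoglobulin segments, unnamed gene models and pseudogenes were left out of the last part. In ILC2-like cells the rule gave 36, 76, 54 and 49 genes past the threshold for Nude, dKO, Id1 and dKO against Id1. The text writes out part of them, picked after their values had been seen; all but 2 that are not reported here were followed through the alternatives. The samples' groups, the tests, the gene lists, this rule and most alternatives were fixed before the data were examined. A further 13 alternatives were added after seeing the data and are named as such.

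The statistics were tested on simulated data with the real means and library sizes, with 50 genes changed by each of the log2 folds 1, 2, 3 and 4. In ILC2-like cells 30%, 84%, 96% and 100% of these were found for Nude, 16%, 60%, 78% and 86% for dKO, and 32%, 82%, 90% and 100% for Id1. In all retained cells a log2 fold of 2 was found for 60%, 58% and 62% of genes. Simulated genes all took the spread of the fitted trend, without variation between genes of like level. The real fit of all retained cells had few prior degrees of freedom (2.34), so these shares do not carry over to it. In ILC2-like cells the infinite prior rests on 1 residual degree of freedom. The shares there hold only if real genes of like level vary alike, which so few libraries cannot show. An 8-fold change of a cluster's share was found in 4 of 300 simulated cases (1.3%). The WT libraries were checked for one library deposited more than once. The closest pair, WT replicates 1 and 2, differed by a chi-square of 14.8 per degree of freedom over 11857 genes, so all 3 were counted as samples.

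Alternatives covered the test (DESeq2 1.42.0), its size factors, the filters on genes and cells, doublets, equal numbers of cells, the clustering, thinning, leaving out each WT library, the barcode set as a block, and others named with their results. UMIs per gene come from short tags, so genes with near-identical copies (H2-Q7, Hspa1b, Ifitm2 and Ifitm3, Trbc1 and Trbc2, ribosomal protein genes) are uncertain where the counting could split them. The T cell receptor segments and the other clusters were compared only as shares.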

Results

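Blood cells without lineage markers and with Thy1, the sort gate of the labels, were profiled from WT, Nude, dKO and Id1 mice to compare ILC2, the group 2 innate lymphoid cells that make type 2 cytokines, between strains. The series title concerns export of ILC precursors from the thymus to blood, and the athymic Nude strain bears on that question. The 3 WT libraries held 1940, 3228 and 1563 cell barcodes with 10467139, 21287792 and 9614029 UMIs. The Nude library held 5132 barcodes with 27926066 UMIs, the dKO library 6723 with 15806007 and the Id1 library 3063 with 19520920. Median UMIs per barcode were 5156, 5638 and 4647 in WT, 4643 in Nude, 2220 in dKO and 5785 in Id1, so a dKO cell was sampled less deeply than any other. Cell barcodes were shared beyond chance between some libraries, 122 between WT replicate 3 and Nude, 103 between WT replicate 3 and Id1, 99 between Nude and Id1 and 41 between WT replicates 1 and 2, against 0 to 8 for the other pairs. The libraries thus fall into a set of WT replicates 1 and 2 and a set of WT replicate 3, Nude and Id1, with dKO in neither. Within its set, Nude or Id1 has only WT replicate 3 to be compared with, and dKO has no WT library.

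Tcf3, Tcf12, Id1 and Foxn1 were read first. The label Id1 is also the name of a gene, which encodes an inhibitor of E proteins; Tcf3 and Tcf12, which encode E proteins, transcription factors of early lymphocytes, were chosen for that link and not from a label. Over all retained cells, Tcf3 (ENSMUSG00000020167, chromosome 10, 80409514 to 80433647, mm10) stood at 52.8, 57.0 and 73.2 CPM in WT, 53.6 in Nude, 13.6 in dKO and 54.0 in Id1 (dKO log2 fold change −2.17 ± 0.27 SE, adjusted p = 0.12). Tcf12 (ENSMUSG00000032228, chromosome 9, 71842688 to 72111871) stood at 115.1, 113.0 and 109.5 CPM in WT and at 51.1 in Nude, 55.7 in dKO and 69.4 in Id1, with adjusted p of 0.0763 in Nude. Transcript of Id1 (ENSMUSG00000042745, chromosome 2, 152736251 to 152737410) was at 0.305, 0.42 and 9.88 CPM in WT, 3.32 in Nude, 1.07 in dKO and 65.8 in the Id1 library (log2 fold change 4.27, adjusted p = 0.575). No UMI of Foxn1 (ENSMUSG00000002057, chromosome 11, 78357577 to 78386558), the thymic epithelial factor disrupted in Nude mice, was counted in any of the 6 libraries. A UMI tag outside a deleted part of a gene checks nothing about the deletion, and none of these values passed the edgeR threshold.

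The makeup of the libraries differed, but each strain other than WT is 1 library, so strain and library cannot be separated. ILC2-like cells (clusters 6, 16 and 18, with Il1rl1, Il17rb and Gata3 or Ccr10, Klrg1 and Arg1 among their leading genes) were 0.266%, 4.83% and 5.01% of retained cells in WT (mean 3.37% ± 2.69 SD, n = 3). They were 14.04% (95% interval 13.1 to 15.04) in Nude, 2.39% (2.04 to 2.79) in dKO and 56.8% (55.005 to 58.6) in Id1. Cells of cluster 3, the only one named gamma-delta T-like, with Cd163l1, Blk and Tcrg-V6 among its leading genes, were 10.1%, 11.9% and 17.6% in WT, 0.279% (0.153 to 0.468) in Nude, 0.35% (0.222 to 0.525) in dKO and 7.57% (6.65 to 8.57) in Id1. They are a part of the cells with Trdc, which was also in 96.8%, 86.4%, 98.0% and 85.9% of cells in the unnamed clusters 0, 1, 4 and 7 and in 64.6% and 68.4% of those in the dKO clusters 10 and 11. ILC3-like cells (cluster 24, Cd3d detected in 41.3% of its cells) made up 7.18% (6.48 to 7.93) of Nude cells, against 0%, 0.125% and 0.066% in WT, 0.046% in dKO and 0.8% in Id1. NK/ILC1-like cells (clusters 13 and 20) were 4.09% (3.56 to 4.68) of Nude cells and 0.106%, 1.26% and 0.264% of WT cells. No cell was named so in dKO, where 3 counts of the total are 0.046%, or in Id1, where they are 0.1%. The Cd3d limit kept this name from clusters 1, 7 and 25, with 72.2%, 50% and 50% of the NK list raised. Cluster 1 held 2.55%, 1.44% and 0.329% of WT, 5.07% of Nude, 21.66% of dKO and 0% of Id1 cells. Cluster 7 held 12.4%, 11.3% and 1.85% of WT cells and at most 0.399% of any other library. Cluster 25 held 1.005% of dKO cells only. The shares are of sorted cells and were not tested at equal depth.

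Basophil-like cells (cluster 23) were 19.96% of WT replicate 3, 0.031% of WT replicate 2 and 0 of 1881 cells in WT replicate 1, and they were 5.33% of Nude, 0.183% of dKO and 0.967% of Id1 cells. Monocyte-like cells (cluster 9) were 0.898% of Nude cells and at most 0.329% of any other library. With WT libraries this far apart, none of the 6 named classes passed the edgeR test in any strain. The log2 share ratio of ILC3-like cells in Nude was 6.67 ± 1.58 SE (adjusted p = 0.123), that of cluster 3 cells −5.54 ± 1.33 in Nude and −5.22 ± 1.30 in dKO (both 0.123) and −0.80 in Id1 (0.645). For ILC2-like cells it was 2.06 ± 1.66 in Nude (0.485), −0.49 ± 1.86 in dKO (0.889) and 4.07 ± 1.65 in Id1 (0.247). Within the set of WT replicate 3, Nude and Id1, the ILC2-like share was 5.01%, 14.04% and 56.8%, with 1 library per strain.

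Clusters without a name held 89.3%, 81.8% and 56.8% of WT cells, 68.2% of Nude, 97.0% of dKO and 33.8% of Id1 cells. Unnamed clusters with Cd3d, a subunit of the T cell receptor complex, in most cells held 88.6%, 73.0% and 42.7% of WT cells, 12.4% of Nude, 93.9% of dKO and 12.5% of Id1 cells. Unnamed clusters with Cd3d in a minority of cells held 53.6% of Nude cells and 18.8% of Id1 cells, 3.001% in dKO and 0.319%, 2.10% and 0.198% in WT. The remainder, clusters 12 and 15 with thymocyte genes such as Dntt and Rag1, made up 0.425%, 6.68% and 13.9% of WT cells, 2.15% of Nude, 0.122% of dKO and 2.53% of Id1 cells. All 76 Id1 cells and 77 of the 100 Nude cells of cluster 12 carried barcodes of WT replicate 3. All 7 WT replicate 1 cells of cluster 12 carried barcodes of WT replicate 2, so the share in WT replicate 1 rests nearly on these. Cluster 21, led by Ifng and Klrb1b, held 1618 cells of which 1610 were Nude. Cluster 14, led by Igfbp4 and Id1, held 502 Id1 cells of 512, and clusters 10 and 11, led by Gdpd3, held 1912 and 2616 dKO cells. A cluster of nearly 1 library may be that library rather than a kind of cell.

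**Figure D1:**
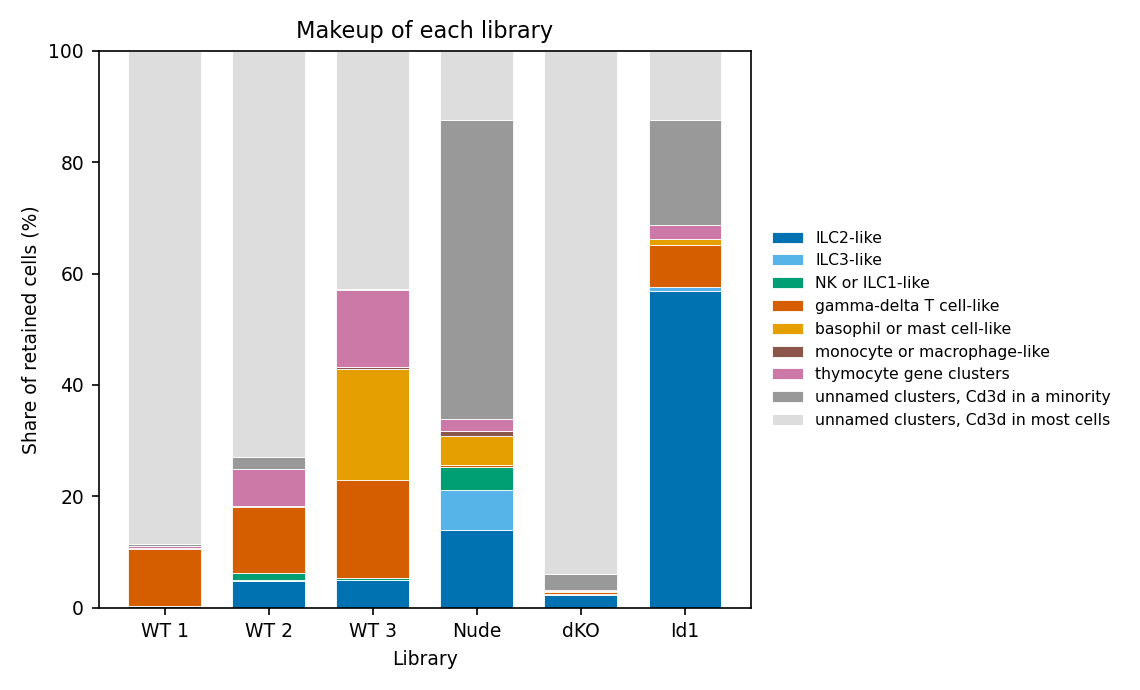
Stacked bars give the share of retained cells (%) in each named class and in the unnamed clusters, 1 bar per library. ILC2-like cells reach 56.8% in the Id1 library against 0.266% to 5.01% in the 3 WT libraries.

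In ILC2-like cells of the dKO strain, 11 of 20 T cell receptor, 7 of 17 thymocyte and 7 of 17 naive lymphocyte genes were higher than in WT, and 9 of 19 ILC2 identity genes were lower. As lists, none of these passed with an estimated correlation (adjusted p = 0.427 each). Cd3e, a signalling subunit of the T cell receptor complex (ENSMUSG00000032093, chromosome 9, 44998740 to 45009627), stood at 454 CPM in dKO against 23 and 2.39 in the WT libraries (log2 fold change 4.73 ± 0.32 SE, adjusted p = 1.82e-46). Klrg1, an inhibitory receptor of mature ILC2 (ENSMUSG00000030114, chromosome 6, 122270596 to 122282882), stood at 7.597 CPM against 268 and 291 (−5.19 ± 0.48, 9.69e-24). In all, 281 genes rose and 292 fell of 8990 tested, with 157 dKO cells against 154 and 76 WT cells from 2 libraries. With the 5 ILC2-like cells of WT replicate 1 added 160 genes passed, and at Leiden resolution 2 there were 60. All 573 lay outside the values of both WT libraries.

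Of 20 tested members of the T cell receptor list, 11 rose and none fell in dKO (11 and 2 adjusted over the list alone; camera adjusted p = 1.18e-17, adjusted p = 0.427 with an estimated correlation). They included the gamma chain constant gene Tcrg-C2 (5.19 ± 0.38 on the log2 scale), the chain Cd247 (2.55, adjusted p = 7.59e-06) and Themis, a T cell signalling protein (3.29, 1.38e-07). Of 17 thymocyte genes 7 rose and none fell (8 and 0 adjusted over the list alone; 7.5e-11, adjusted p = 0.427 with an estimated correlation). Hes1, a Notch target, reached 382 CPM against 2.3 and 85.9 in WT (3.77 ± 0.31, 7.26e-31). Cd24a, a surface protein of immature cells, had 27 UMIs against 2, a CPM ratio of 44.2 (95% counting interval 11.1 to 383). Of 17 naive lymphocyte genes 7 rose and 1 fell (7 and 2 adjusted over the list alone; 4.67e-08, adjusted p = 0.427 with an estimated correlation). They included Igfbp4 (104.5 CPM against 10.7 and 19.1) and Lef1, a factor of the same family as Tcf7 (1.88), with S1pr1, an egress receptor, at 283 CPM against 122 and 74.0 (1.45, 9.06e-06). Outside these lists, the phosphodiesterase gene Gdpd3 had 51 UMIs against 3 (ratio 55.6, 18 to 279), and the granzyme gene Gzma rose by 4.51 on the log2 scale. Igfbp4, S1pr1 and Gdpd3 are also leading genes of cluster 10, which held 29.1% of dKO cells. Gzma leads cluster 1, which held 21.66%. RNA or doublets of those cells could add to these rises, and the ratio check made for Cd3e was not made for these genes.

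Of 19 ILC2 identity genes tested in dKO, 1 rose and 9 fell (1 and 12 adjusted over the list alone; 6.21e-09, adjusted p = 0.427 with an estimated correlation). Arg1, an arginine-degrading enzyme of ILC2 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), fell from 244 and 224 CPM to 19.0 (−3.63 ± 0.41, 4.52e-16). The cytokine genes Il5 and Csf2 had 0 UMIs in dKO, at least 3.5-fold and at least 5.3-fold lower than in WT, and the neuropeptide gene Calca had 2 against 73 (ratio 0.0897, 0.0107 to 0.336). All 4 ILC3 genes that passed, of 8 tested, fell (0 and 6 adjusted over the list alone; 3.95e-08, adjusted p = 0.427 with an estimated correlation), with Tmem176a at −2.24. Of 24 trafficking genes 3 rose and 9 fell (3 and 15 adjusted over the list alone; 0.00048, adjusted p = 0.428 with an estimated correlation). The skin-homing receptor Ccr10 (ENSMUSG00000044052, chromosome 11, 101172997 to 101175443) fell from 331 and 146 CPM to 7.597, and the adhesion receptor Cd44 (−3.05 ± 0.45) and the chemokine receptor Ccr2 (−1.79) fell too. MHC class II genes fell in 4 of 6 members (0 and 4 adjusted over the list alone; 2.98e-08, adjusted p = 0.428 with an estimated correlation), with Cd74 at 77.9 CPM against 571 and 525. The B cell list, which shares those genes, fell in 4 of 5 (0 and 4 adjusted over the list alone; 2.16e-08, adjusted p = 0.443 with an estimated correlation). Id2, the inhibitor of E proteins required by all ILCs, dropped from 1321 and 1275 CPM to 245 (−2.41 ± 0.26, 1.75e-17), and Tcf3 stood at 7.597 CPM with 4 UMIs against 32.2 and 47.7 (−2.29 ± 0.66, 0.0148).

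Ribosomal protein genes rose in 10 and fell in 1 of 47 (16 and 1 adjusted over the list alone; 0.00297, adjusted p = 0.428 with an estimated correlation) and glycolysis genes fell in 3 of 15 (0 and 7 adjusted over the list alone; 0.00566, adjusted p = 0.615 with an estimated correlation). The other lists in dKO did not pass: interferon, ILC precursor and cell cycle (0.0573 each), mitochondrially encoded (0.147), activation (0.401), MHC class I and E and Id proteins (0.424 each), myeloid (0.81), and immediate early and NK (0.882 each). The NK list had a median of −0.82 and a test upward, and the interferon, activation, MHC class I and myeloid lists had a positive median and a negative mean. DESeq2 called 13 genes up and 35 down, all 48 among the 573 and in the same direction, and in cells thinned to 1000 UMIs edgeR called 0 genes, with 421 of the 423 measured in the same direction. Cluster 6 held 92.4% of dKO ILC2-like cells against 24.7% and 52.6% in WT, where cluster 16 held 74.0% and 43.4%. Within cluster 6 alone 183 genes passed, and the fold was 3.95 for Cd3e, −4.00 for Klrg1, −2.68 for Id2 (1.77e-11), −1.92 for Cd74 (0.577) and 0.40 for the chemokine Ccl5 (0.678), which fell in all ILC2-like cells at −2.48. By list within cluster 6, T cell receptor genes rose in 10 and fell in 1 of 19, ILC2 identity genes fell in 8 of 17, and trafficking genes rose in 2 and fell in 3 of 19 with a median of −0.30. At Leiden resolution 2, 117 of the 145 dKO cells of cluster 6 fell in an unnamed cluster without a WT cell, and 14 in a cluster with 34 and 36 WT cells; Cd3e was seen in 8 of these 14 (57.1%, 28.9 to 82.3) and in 1 cell of each WT library there. Of all dKO cells 22 were named ILC2-like at that resolution, with a Cd3e fold of 3.78. The dKO ILC2-like cells held Y-linked UMIs in only 2 of 157 cells (1.27%, 0.15 to 4.53), against 21.4% and 23.7% of those in WT. Among cells with Xist and no Y-linked UMI 33 genes passed. All 570 of the called genes measured there kept their direction, with a median absolute log2 fold change of 1.56 against 1.49 in all ILC2-like cells.

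**Figure D2:**
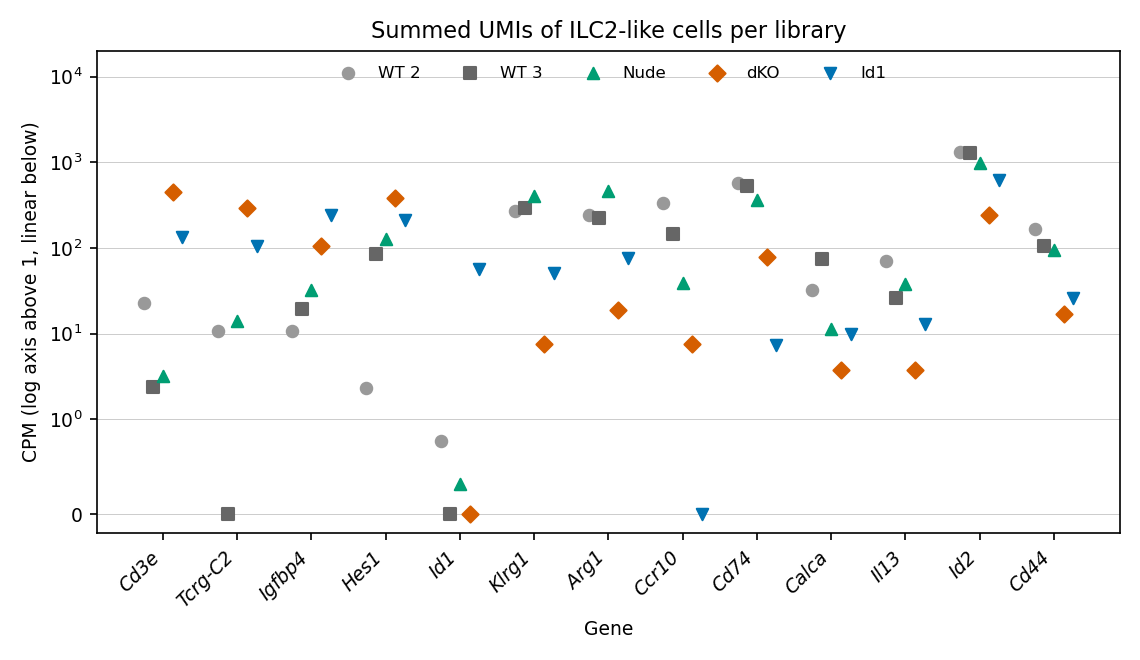
Points give CPM of 13 genes (log-like axis that includes 0) from summed UMIs of ILC2-like cells, 1 point for each of 5 libraries. Cd3e lies at 454 CPM in dKO and 136 in Id1, against 23 and 2.39 in WT.

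In ILC2-like cells of the Id1 strain, Id1 transcript was found with rises of 5 of 17 thymocyte and 4 of 17 naive lymphocyte genes, while 5 of 6 MHC class II and 7 of 24 trafficking genes were lower than in WT. As lists, none of these passed with an estimated correlation (adjusted p = 0.353 each). Cluster 16, with Ccr10, Klrg1 and H2-Eb1 among its leading genes, held 74.0% and 43.4% of WT and 1.4% of Id1 ILC2-like cells. Id1 itself had 645 UMIs in 1704 cells against 1 in 230 WT cells, a CPM ratio of 96.7 (17.3 to 3830). Cd74, the MHC class II invariant chain, stood at 7.40 CPM against 571 and 525 in WT (−6.21 ± 0.34 on the log2 scale, adjusted p = 8.35e-71), and Ccr10 had 0 UMIs against 493, at least 1095.6-fold lower. In all, 125 genes rose and 224 fell of 8990 tested, and 345 of these 349 lay outside both WT values. With the 5 ILC2-like cells of WT replicate 1 added 147 genes passed, and at Leiden resolution 2 there were 161.

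Of 20 T cell receptor genes 9 rose and none fell (12 and 2 adjusted over the list alone; camera adjusted p = 9.68e-12, adjusted p = 0.353 with an estimated correlation). Cd3e stood at 136 CPM against 23 and 2.39 (2.98 ± 0.31, 5.76e-19), Tcrg-C2 at 105 against 10.7 and 0 (3.73 ± 0.37), and Trdc, the delta chain constant gene (ENSMUSG00000104876, chromosome 14, 54142851 to 54148868), at 165 against 66.7 and 14.3 (1.74, 8.29e-09). Of 17 thymocyte genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; 5.5e-09, adjusted p = 0.353 with an estimated correlation), with Cd24a at 927 UMIs against 2 (ratio 69.5, 19.2 to 575), Hes1 at 209 CPM against 2.3 and 85.9 (2.90 ± 0.30) and Sox4, a factor of progenitors, at 2.01. Naive lymphocyte genes rose in 4 of 17 (6 and 2 adjusted over the list alone; 6.01e-06, adjusted p = 0.353 with an estimated correlation). Igfbp4 stood at 245 CPM against 10.7 and 19.1 (4.23 ± 0.32, 1.67e-35). It also leads cluster 14, which held 16.7% of Id1 cells, so RNA or doublets of those cells could add to it.

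MHC class II genes fell in 5 of 6 members in Id1 (0 and 5 adjusted over the list alone; 1.28e-67, adjusted p = 0.353 with an estimated correlation), among them H2-Eb1 (−7.38 ± 0.45), H2-Aa (−6.67) and H2-Ab1 (−5.25). The overlapping B cell list fell in 3 of 5 (0 and 4 adjusted over the list alone; 4.01e-38, adjusted p = 0.353 with an estimated correlation). Of 19 ILC2 identity genes 2 rose and 6 fell (4 and 8 adjusted over the list alone; 3.91e-06, adjusted p = 0.353 with an estimated correlation). The type 2 cytokine genes Il13 (ENSMUSG00000020383, chromosome 11, 53631324 to 53634702; 70.5 and 26.3 CPM in WT, 12.97 in Id1) and Il5 (−4.75 ± 0.69) fell, as did Klrg1 (51.4 CPM, −2.44 ± 0.27) and Calca (−2.27 ± 0.40). Of 24 trafficking genes 2 rose and 7 fell (5 and 9 adjusted over the list alone; 4.5e-07, adjusted p = 0.353 with an estimated correlation), with the epithelial-binding integrin Itgae at −4.44, Cd44 at −2.44 and Ccr6 at 1 UMI against 85 (ratio 0.00176, 4.42e-05 to 0.0101). ILC3 genes fell in 2 of 8 (0 and 3 adjusted over the list alone; 4.09e-06, adjusted p = 0.439 with an estimated correlation). NK genes rose in 1 and fell in 3 of 9 (2 and 5 adjusted over the list alone; 9.76e-05, adjusted p = 0.477 with an estimated correlation), with Ccl5 at −2.86. Id2 stood at 612 CPM, under the WT values of 1321 and 1275 (−1.09 ± 0.23, 0.000147).

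Lists that did not pass in Id1 were ILC precursor and cell cycle (0.0598 each), activation (0.168), E and Id proteins and myeloid (0.17 each), ribosomal (0.594), MHC class I (0.609), mitochondrially encoded (0.689), interferon and glycolysis (0.759 each) and immediate early (0.949). In Id1 the interferon list had a negative median and a positive mean, and the immediate early list had both positive with a test downward. DESeq2 called 4 genes up and 34 down, all 38 among the 349, and 0 genes passed edgeR in thinned cells with all 167 measured genes in the same direction. Against WT replicate 3 alone, the WT library of its barcode set, 345 of the 349 genes kept their direction and 3 turned. This count is no separate check, since genes outside both WT values keep their direction against either library. WT replicate 2 alone decides Cxcr3 (−2.83 with both, 2.19 without it). Cluster 6 held 98.1% of Id1 ILC2-like cells against 24.7% and 52.6% in WT. Within cluster 6, 92 genes passed, with folds of 2.13 for Cd3e (3.64e-06), 3.64 for Igfbp4, −1.24 for Klrg1 (0.0119), −2.91 for Il13 (1.38e-10), −1.58 for Cd74 (0.756) and −0.05 for Ccl5. By list within cluster 6, trafficking genes rose in 2 and fell in 2 of 19 with a median of 0.18, ILC2 identity genes fell in 7 of 17, and T cell receptor genes rose in 5 and fell in 1 of 19.

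In ILC2-like cells of Nude mice fewer genes differed from WT, 34 higher and 39 lower of 8990, and the T cell receptor list did not move as a whole. Ifitm3, an interferon-induced membrane protein, stood at 280 CPM against 29.9 and 26.3 (3.28 ± 0.29, adjusted p = 4.42e-26), and the prohormone convertase gene Pcsk1 at 8.37 against 150 and 19.1 (−3.56 ± 0.39, 6.35e-17). Ccr10 fell from 331 and 146 CPM to 38.6 (−2.70 ± 0.29, 2.13e-17). Of 20 T cell receptor genes, Tcrg-C1 rose and 2 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.196). Cd3e stood at 3.22 CPM and Trdc at 19.3, each between the WT values of 23 and 2.39 and of 66.7 and 14.3. Their calls (−2.40 ± 0.52, 0.001; −1.35, 0.00745) rest on WT replicate 2, since against WT replicate 3 alone the folds were 0.36 and 0.42. For Tcrg-C1, the share of thinned Nude cells with a UMI was close to that of WT replicate 3 and above that of WT replicate 2.

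Of 24 trafficking genes 3 fell in Nude (0 and 5 adjusted over the list alone; 7.53e-06, adjusted p = 0.687 with an estimated correlation), with Itgae at −2.37 and Ccr6, a mucosal chemokine receptor, at −2.34. MHC class I genes were higher as a list (3.15e-05, adjusted p = 0.687 with an estimated correlation), with 1 of 14 members past the threshold, H2-Q7 at 0.81 (7 adjusted over the list alone). Of 14 ILC precursor genes 1 rose and 3 fell (1 and 4 adjusted over the list alone; 0.0371, adjusted p = 0.687 with an estimated correlation). Kit, the stem cell factor receptor, was the rise (109.7 CPM against 21.5 and 62.1, 1.68), and Tcf7, a factor of T and ILC precursors, fell from 156 and 115 CPM to 61.8 (−1.17, 0.00383). Thymocyte genes rose in 3 and fell in 1 of 17 (3 and 2 adjusted over the list alone; 0.934), and Hes1 (126 CPM, 2.18 ± 0.31), the Notch target Dtx1 (110 against 23.8 and 50.1) and Cd24a (129 UMIs against 2, ratio 35.8, 9.7 to 298) were the rises. The size of the Hes1 fold rests on WT replicate 2, where Hes1 was far lower than in WT replicate 3. That gap between the WT libraries hardly entered its p-value. ILC2 identity genes rose in 1 and fell in 1 of 19 (1 and 1 adjusted over the list alone; 0.196), Arg1 at 461 CPM against 244 and 224 (0.97 ± 0.24) and Calca at 11.3 against 32.2 and 74.0 (−2.07 ± 0.44). Gzma (3.71 ± 0.47) and Nrgn, a calmodulin-binding protein (292 CPM against 25.3 and 43.0), were higher, while Apobec3, a cytidine deaminase (24.8 against 92.8 and 289), was lower.

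Other Nude lists did not pass: cell cycle (0.1), immediate early (0.103), ribosomal and MHC class II (0.183 each), naive (0.215), mitochondrially encoded (0.244), NK (0.316), activation (0.393), interferon (0.456), ILC3 (0.935), and E and Id proteins, glycolysis, B cell and myeloid (0.647 each). The ILC3, interferon and glycolysis lists had a positive median and a negative mean, and the thymocyte list the opposite. DESeq2 called 2 genes, Ifitm3 and Nrgn, and thinned cells gave 0 by edgeR, with 53 of 54 measured genes in the same direction. Of the 73 genes 68 lay outside both WT values, and 68 kept their direction against WT replicate 3 alone. The second count is no separate check, since a gene outside both WT values keeps its direction against either library. With the 5 ILC2-like cells of WT replicate 1 added 34 genes passed, and at Leiden resolution 2 there were 25. Cluster 18, with Arg1, Ifitm3 and Nrgn among its leading genes, held 15.9% of Nude ILC2-like cells against 1.3% and 3.9% in WT, cluster 6 held 43.5% and cluster 16 held 40.6%. At Leiden resolution 2 a cluster of 246 cells led by the platelet gene Pf4, with Ifitm3, Arg1 and Nrgn, was named platelet-like and not ILC2-like; it held 120 Nude and 114 Id1 cells, 106 of the latter from cluster 6, so some cells named ILC2-like carry platelet transcripts. Within cluster 6, 21 genes passed, with Ifitm3 at 3.32 (7.19e-07), Hes1 at 1.52 (0.00247) and Calca at −2.89, but Nrgn at −1.02 (0.679), Cd7 at 0.57 and Tcf7 at −0.52. None of 19 trafficking genes (median −0.17) and none of 14 ILC precursor genes passed there.

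The dKO and Id1 strains were tested against each other in ILC2-like cells, where 123 genes were higher in dKO and 97 lower. T cell receptor subunits were higher in dKO: Cd3d (ENSMUSG00000032094) at 125 CPM against 18.6 (2.75 ± 0.37, adjusted p = 1.22e-10), Cd3g at 469 against 91.6 (2.36 ± 0.29, 4.55e-13) and Cd3e at 454 against 136 (1.74 ± 0.28, 4.9e-07). Unnamed clusters with Cd3d in most cells held 93.9% of dKO and 12.5% of Id1 cells. RNA or doublets of those cells could raise Cd3d and Cd3g in dKO ILC2-like cells, which was not tested for these genes. Gzma (4.01), the interferon-induced GTPase gene Iigp1 (3.42), Gdpd3 (6.17 ± 0.74), Tnfaip3, a brake on NF-kB (1.79), and Lef1 (1.66) were higher as well. Gzma is a leading gene of cluster 1, and Iigp1 and Gdpd3 of cluster 11. Both clusters are mostly dKO cells, so the same limit holds for these genes. Id1 transcript, at least 9.9-fold lower, Arg1 (−1.99), Klrg1 (−2.75), Id2 (−1.32), Ccr2 (−2.07 ± 0.33) and Igfbp4 (−1.23, 0.00975) were lower. Trim12a, a gene of the TRIM5 family (ENSMUSG00000066258, chromosome 7, 104299894 to 104315466), had 1 UMI in dKO against 1036 (ratio 0.0211, 0.000533 to 0.118).

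By list, MHC class II genes were higher in dKO than in Id1 in 4 of 6 (4 adjusted over the list alone; 5.66e-13), NK genes in 2 of 9 (2; 0.000803), T cell receptor genes in 5 with 1 lower of 20 (6 and 3 adjusted over the list alone; 0.00102), thymocyte genes in 2 of 17 (4 and 1; 0.0416) and naive genes in 2 with 1 lower of 17 (4 and 2; 0.0487). ILC2 identity genes were lower in 4 of 19 (1 higher and 5 lower adjusted over the list alone; 3.17e-05), ILC3 genes in 3 of 8 (0 and 3; 0.00205), E and Id proteins in 3 of 14 (2 and 5; 0.0158) and glycolysis in 1 of 15 (0 and 2; 0.00336). B cell (8.38e-05), ribosomal (0.0158, no member past the threshold), activation and interferon (0.0401 each) passed too; the last pair had medians of 0.25 and 0.13 and means of −0.09 and −0.05. All 13 had adjusted p = 0.471 with an estimated correlation. Trafficking (0.418), ILC precursor (0.464), mitochondrially encoded (0.311), cell cycle (0.371), myeloid (0.619; median −0.42 with a test upward), and immediate early and MHC class I genes (0.799 each) did not pass. DESeq2 called 8 genes up and 2 down. Within cluster 6 Cd74 was at −0.34 (0.939). Among cells with Xist and no Y-linked UMI 1 gene passed, while 216 of the 217 genes measured there kept their direction and 0 turned. The Y-linked gene Eif2s3y, with 1 UMI in dKO, is among the 97.

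T cell receptor transcripts in ILC2-like cells were also read per cell, after thinning to 1000 UMIs, in 154 and 76 WT, 702 Nude, 155 dKO and 1704 Id1 cells (median UMIs before thinning 7358, 5015, 4339, 3346 and 6026). Cd3e was seen in 32.3% (24.98 to 40.2) of dKO and 12.5% (10.97 to 14.2) of Id1 cells, in 0.43% (0.09 to 1.24) of Nude cells and in no WT cell, where 3 counts of the total are 1.95% and 3.95%. Cd3g was seen in 35.5% of dKO, 7.92% of Id1, 10.4% of Nude and 12.99% and 5.26% of WT cells, and Cd247 in 5.81%, 3.29%, 0.43%, 0% and 0%. Trdc was seen in 15.5% (10.2 to 22.2) of dKO and 15.6% (13.9 to 17.4) of Id1 cells, against 0.71% in Nude and 3.25% and 2.63% in WT. Tcrg-C1 was found in 44.8% of Id1, 36.8% of Nude, 18.1% of dKO and 12.3% and 35.5% of WT cells, and Trbc in 63.0% to 87.6% of cells in all 5 libraries. The alpha chain gene Trac was seen in no dKO cell, where 3 counts of the total are 1.94%, and in at most 1.3% of cells elsewhere.

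Basophil-like cells, which should lack Cd3e, had it in 13.5% of WT replicate 3 cells (median 4161 UMIs), 0 of 267 Nude cells (2971), 2 of 12 dKO cells (16.7%, 3047) and 6 of 26 Id1 cells (23.1%, 8.97 to 43.7; 9478). The Id1 share of 12.5% in ILC2-like cells lies within the interval of these 26 deeper cells. Cd3d was in 1.23% of Id1 ILC2-like cells and 19.2% of basophil-like ones, and in 7.74% and 8.33% in dKO. Xist and a Y-linked UMI were found together in 24.14% of Id1 basophil-like cells, against 3.03% of the library. These shares are not at equal depth. They may come from doublets or from free RNA, which were not measured apart. Free RNA keeps its genes in a fixed ratio, so Cd3e and Cd3d UMIs were compared: 239 to 66 in dKO ILC2-like cells and 1557 to 214 in those of Id1. That ratio was 3.60 times (2.73 to 4.80) the one in the dKO clusters with Cd3d in most cells, and 14.76 times (12.79 to 17.11) in Id1. It was 0.94 times (0.58 to 1.49) in WT replicate 2 and 0.60 times (0.27 to 1.22) in Nude. These intervals, and those by cluster, cover UMI counting alone and not variation between cells, and take the reference ratio as fixed. By cluster, the ratio was 4 (3 to 5.42) in cluster 6 and at most 1.14 in the other dKO clusters with at least 20 cells and 20 of these UMIs. In Id1 it was 7.25 (6.28 to 8.41) in cluster 6, 4.34 (3.70 to 5.12) in cluster 14 and at most 1.06 in the others.

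**Figure D3:**
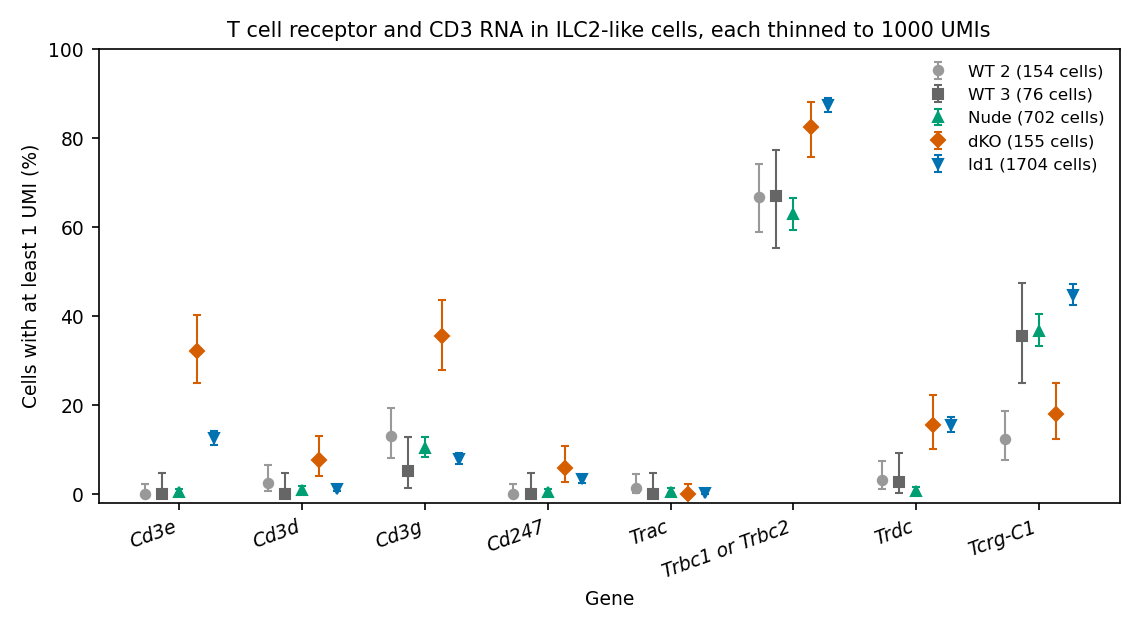
Points give the percentage of ILC2-like cells with at least 1 UMI of each of 8 genes after thinning to 1000 UMIs, 1 point per library with its exact 95% interval. Cd3e is in 32.3% of dKO and 12.5% of Id1 cells and in 0.43% of Nude cells.

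Cluster 4, with Cd3d in 98.2% and Trdc in 98.0% of its 2341 cells and Ly6c2 and Gzmm among its leading genes, could be compared in all 6 libraries, but its cells were not alike. At Leiden resolution 2, 69.9% of its Nude and 92.3% of its Id1 cells fell in a cluster with Cd8b1 among its leading genes, which took 1.7%, 1.6% and 1.1% of its WT and 5.7% of its dKO cells. Another took 80.9%, 78.7% and 71.8% of the WT, 54.7% of the dKO, 11.4% of the Nude and 6.1% of the Id1 cells. The folds of cluster 4 are thus not between matched cells. In Nude 107 genes rose and 35 fell of 9536, in Id1 202 and 144, and in dKO, with 53 cells, 6 and 13. Lgals3, encoding galectin-3, rose in Nude from 10.6, 12.2 and 5.08 CPM to 207 (4.31 ± 0.21, adjusted p = 5.84e-10) and in Id1 (3.87). The coreceptor chain Cd8b1 rose in Nude (5.24), dKO (6.42 ± 0.67) and Id1 (8.46 ± 0.23), Ccr2 in Nude (3.34 ± 0.21) and Id1 (3.39), and the scavenger receptor gene Cd163l1 in Nude (3.82) and Id1 (3.92). Ikzf2, which encodes the factor Helios, fell in Nude (−2.27 ± 0.22) and Id1 (−3.91 ± 0.23), as did the integrin Itga4 (−1.57 and −1.54) and the kinase Tec (−1.92 and −3.22). Id3, an E protein inhibitor, fell in Nude (−2.30) and had 0 UMIs in Id1, at least 27.7-fold lower, while Id1 (6.97 ± 0.37) and Id2 (1.38) rose in Id1. In dKO Gdpd3 rose (6.50 ± 0.75, 0.000228), and Trim12a had 0 UMIs against 2223, at least 12.7-fold lower.

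Interferon genes rose in cluster 4 of Nude in 5 of 28 members (9 and 0 adjusted over the list alone; camera adjusted p = 4.28e-09, adjusted p = 0.284 with an estimated correlation) and in Id1 in 4 of 28 (5 and 0 adjusted over the list alone; 0.00127, adjusted p = 0.409 with an estimated correlation), with Usp18 at 1.31 in Nude. ILC3 genes, such as Tmem176b and Cxcr6 (1.83 and 0.99 in Nude), rose in 3 of 4 in both strains (5.79e-07 and 1.56e-07; adjusted p = 0.284 and 0.409 with an estimated correlation). Ribosomal protein genes were lower in dKO (1 of 47 fell, 13 adjusted over the list alone; 3.12e-22, adjusted p = 0.486 with an estimated correlation), and mitochondrially encoded genes fell in 4 of 13 (2 and 8 adjusted over the list alone; 3.1e-08, adjusted p = 0.443 with an estimated correlation). The T cell receptor list of Id1 rose in 5 and fell in 5 of 24 (0.0132), with a median of −0.02, a mean of 0.24 and a test upward. MHC class I (0.00106), ILC2 identity (0.0303), mitochondrially encoded (0.0328) and activation genes (0.0497) also passed in Nude, MHC class I (0.00147) and immediate early genes (0.00956) in dKO, and activation (0.0132), myeloid (0.0248), thymocyte (0.0337), glycolysis and immediate early genes (0.0409 each) in Id1. None passed with an estimated correlation, where the smallest adjusted p was 0.284. Leaving out WT replicate 1 gave 203, 98 and 332 genes for Nude, dKO and Id1, leaving out WT replicate 2 gave 65, 6 and 174, and leaving out WT replicate 3 gave 871, 165 and 1094. With the barcode set as a block 360 genes passed in Nude and 483 in Id1. DESeq2 called 24, 20 and 52.

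Over all retained cells, the sums follow the makeup of each library, and 1 gene passed in Nude and none in dKO or Id1 by edgeR, of 13290 tested. Gadd45g, a stress-induced growth arrest gene, rose in Nude from a WT mean of 5.49 CPM ± 0.661 SD (n = 3) to 188.2 (5.09 ± 0.17, adjusted p = 0.0421); without WT replicate 1 or without WT replicate 2 no gene passed and without WT replicate 3 there were 1636. With the barcode set as a block 413 genes passed in Nude and 54 in Id1. At an unadjusted p under 0.05 there were 3013, 2432 and 1190 genes, and DESeq2 called 1083, 587 and 273. Id3 was among the 5 smallest p in dKO and Id1, at 0.884 and 2.22 CPM against 51.4 ± 0.867 in WT and 8.22 in Nude (−5.85 ± 0.23 in dKO and −4.53 ± 0.21 in Id1, adjusted p = 0.0893 and 0.17). Gdpd3 stood at 133.1 CPM in dKO against 1.09 ± 0.542 (6.99 ± 0.46, 0.103), and Gata3, the main ILC2 factor, at 444 in Id1 against 89.2 ± 13.7 (2.32 ± 0.19, 0.2).

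By list, T cell receptor genes were lower in all Nude cells (0 of 25 past the threshold over all genes tested, 17 lower adjusted over the list alone; camera adjusted p = 1.31e-12, adjusted p = 0.706 with an estimated correlation), as were naive (1.38e-06), thymocyte (2.76e-05), ribosomal (1.08e-05) and mitochondrially encoded genes (0.0391). Higher in Nude were ILC3 genes (9 of 13 adjusted over the list alone; 2.06e-09, adjusted p = 0.622 with an estimated correlation), MHC class II (5.55e-06), glycolysis (0.000289), ILC2 identity (0.00136), ILC precursor (0.00742) and cell cycle (0.0391). In dKO, ILC3 (8 of 13 adjusted over the list alone; 0.000182, adjusted p = 0.85 with an estimated correlation), cell cycle (0.000422), E and Id proteins (0.000616), glycolysis (0.00392), B cell (0.0092), mitochondrially encoded (0.00935) and ILC precursor genes (0.0221) were lower, and interferon (0.000209) and naive genes (0.0019) higher. In Id1, ILC2 identity (6.91e-09, adjusted p = 0.625 with an estimated correlation), platelet (4.96e-05) and ILC3 genes (7.77e-05) were higher, and NK (3.78e-08), T cell receptor (4.96e-05), B cell (7.77e-05), thymocyte (0.00136), cell cycle (0.0115), MHC class II (0.0198) and E and Id protein genes (0.0224) lower. With an estimated correlation, and so with only 2 residual degrees of freedom, none of these lists passed. A list whose median, mean and test differed in sign was found only among those that did not pass. Among markers of other blood cells, neutrophil, erythroid, basophil and myeloid lists did not pass in any strain (smallest adjusted p 0.0537, Id1 neutrophil).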

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

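The tests of free RNA and doublets in both libraries, of cluster 14 cells in Id1, of dKO cells at resolution 2, of inherited segments, of Trim12a and its neighbours in other cell types, and of cluster 12 cells in the Id1 strain were chosen only after the result was seen.

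The dKO and Id1 strains differed from each other, by a direct test in the fit they share, in 220 genes of ILC2-like cells and in 43 genes of cluster 4. In cluster 4 the genes higher in dKO included Ikzf2 (log2 3.42), Fcer1g (5.20) and Itga4 (1.93), and those lower included Klrk1 (−2.07), Cd8b1 (−2.04) and Id2 (−2.45). At resolution 2, 92.3% of the Id1 and 5.7% of the dKO cells of cluster 4 fell in 1 subcluster, so these are not matched cells. Each side of these tests is 1 library, and dKO shares no barcode set with Id1, so strain and library cannot be separated by them. For the 220 genes, 60 passed with the few ILC2-like cells of WT replicate 1 added, and 10 by DESeq2.

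Cd3e in ILC2-like cells of the dKO and Id1 libraries was higher than in WT, and it could be RNA from other cells, depth or a shift between clusters. RNA or doublets of other cells would keep Cd3e and Cd3d in 1 ratio. In dKO the ratio in ILC2-like cells was 3.6 times that of the clusters with Cd3d in most cells (95% interval 2.73 to 4.8). In Id1 it was 14.76 times that of such clusters (12.79 to 17.11), and these intervals cover UMI counting alone. It was also 1.68 times that of Id1 cluster 14 (1.17 to 2.46 over 1000 redraws of cells). These values argue against each of these cell groups as the whole source. Cluster 14 as part of it in Id1 stays open, since its leading genes had a median of 24.6% (quartiles 11.5 and 42.2) of their cluster 14 level in ILC2-like cells, where Cd3e had 43.3%. Depth is argued against in Id1 by the share after thinning, 12.5% against none of 230 WT cells (dKO cells were shallower than WT cells), and a shift between clusters as the whole source by the folds within cluster 6 (2.13 in Id1, adjusted p = 3.64e-06; 3.95 in dKO, adjusted p = 5.19e-24) and by Cd3e in 57.1% (28.9 to 82.3) of the 14 dKO cells that shared a cluster with most of the WT cells at resolution 2, against 2.9% and 2.8% in WT. For the 80.7% of dKO cells of cluster 6 that had no WT cell in their cluster at resolution 2 such a shift stays open, and so do, in both strains, a strain effect, a different origin of these cells and an effect of the single library.

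Clusters with thymocyte genes appeared in the athymic Nude library and in Id1, in 100 and 76 cells of cluster 12. Reads of WT replicate 3 counted under the same barcode account for many of them: all 76 Id1 cells and 77 of the 100 Nude cells carry barcodes of WT replicate 3. Of those that could be matched to a WT replicate 3 cell of the cluster, 100% (69 of 69, 94.8 to 100) in Id1 and 100% (73 of 73, 95.1 to 100) in Nude correlated best with the cell of their own barcode among 108 candidates, where chance gives 0.93%. In Id1, 0 of 76 cells (interval up to 4.7%) had a barcode found in no other library, which argues against cells of this kind in that strain. In Nude 23 cells had such a barcode and 1 of them (4.3%, 0.1 to 21.9) held Dntt, too few to tell whether Nude blood held such cells. Cluster 15 is another case: its 8 Nude cells all held Dntt and shared no barcode. Only 2 of these 8 held Rag1, and 0 held Ptcra (interval up to 36.9%). In cluster 15 of WT replicates 2 and 3, Rag1 was in 73.1% and 68.93% and Ptcra in 83.45% and 70.87% of cells.

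In dKO 10 genes stood at 10% or less of their level in every other library, against 0 genes by the same rule in Nude and 1 in Id1. Fewer UMIs per dKO cell are argued against, since the median log2 fold change of these genes was −5.23 after thinning. Trim12a, Trim5 and Trim30d lie within 1 Mb of each other on chromosome 7 (3 of 10 genes, against a median of 0 and a highest value of 4 in 1000 random draws), which is consistent with an inherited segment that differs from the reference strain or is not transcribed. A mix of the cell types seen in WT is argued against for these 3 genes together, and so mainly for Trim12a. Of the WT clusters with at least 20 cells, they were lowest in cluster 12 (105 UMIs, of which 92 were Trim12a). That cluster held 10.18 times the CPM of all dKO cells (27.89, 22.81 to 33.76, against 2.74, 1.99 to 3.7). Trim5 and Trim30d had only 9 and 4 UMIs there, so such a mix stays open for each of them alone. The other 7 genes (Blk, Ccr6, Cd163l1, Cryba4, Il17re, Kcnk1 and Plxnd1) had a median of 92.2% (74.9 to 96) of their WT UMIs in gamma-delta T-like and ILC3-like cells. The small share of those cells in dKO may account for them. Blk, Cd163l1, Cryba4, Kcnk1 and Ccr6 are leading genes of these clusters, so the median was partly set by how the clusters were formed. It cannot separate fewer such cells from cells without these genes that fell in other clusters.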

How the results depend on the processing

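The alternatives chosen only after the result was seen were those with the highest doublet scores left out, cells thinned to 1000 UMIs for gene counts, clusters left out of all retained cells, all 6 libraries in ILC2-like cells, the largest ILC2-like cluster, fry, cells with shared barcodes left out, clusters tested by number, cells with Xist and no Y-linked UMI, the barcode set as a block, and those of cluster 4; the others were planned. No paired analysis was possible by replicate number because only WT has more than 1 library. The set of libraries that share barcodes could be a block for Nude and Id1, with 1 residual degree of freedom in all retained cells and cluster 4 and 0 in ILC2-like cells; dKO is in neither set, so its values were not read from that fit. Of 4437 values of single genes 3762 had a test, of which 2751 kept direction and call, 986 kept direction and lost the call and 25 turned. Of the 675 folds without an adjusted p, 354 stayed within 1 SE, 298 moved further and 23 turned. Of 366 values of single lists 200 were the same and 165 weaker, and 1 turned, cell cycle genes in all Nude cells with the barcode set as a block (adjusted p = 0.59). Where nothing else is said, the cause was not tested. Leaving out a WT library in ILC2-like cells, or centring values per library, left 1 WT library and no residual degree of freedom, so those give folds without a test. ILC2-like cells had the fewest UMIs in dKO (median 3287), which bears on the shares of cells with a UMI that were not thinned. The low number of ILC2-like cells (5 in WT replicate 1, 157 in dKO) may limit the calls, but how far was not tested. Thinning left no call there, and in all retained cells it raised the counts; the cause was not tested. Leaving out cells with shared barcodes changed none of the 211 gene values followed in ILC2-like cells. It made 71 of 73, 570 of 573, 348 of 349 and 217 of 220 calls again, and Leiden resolution 0.5 made 64, 524, 318 and 190 again. Leiden resolution 2 made only 19, 49, 143 and 23 again, with 7, 41, 4 and 13 in the opposite direction. All 6 libraries made 30, 156, 145 and 60 again.

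Counts of genes in ILC2-like cells, in the order Nude, dKO, Id1 and dKO against Id1, were 2, 48, 38 and 10 by the DESeq2 Wald test, 26, 321, 118 and 99 with equal cells per library, 25, 60, 161 and 33 at Leiden resolution 2 and 0, 0, 0 and 0 in thinned cells. They were 34, 160, 147 and 60 with all 6 libraries and 2, 33, 32 and 1 in cells with Xist and no Y-linked UMI; in the largest cluster they were 21, 183 and 92 for the 3 strains against WT. Fewer cells entered the last 2 and the equal-cell setting.

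In all retained cells no filter on low counts gave 35 genes for Nude and 1 for dKO, and the DESeq2 Wald test gave 1083, 587, 273 and 535. Thinned cells gave 175, 6, 9 and 8, and the barcode set as a block 413 for Nude and 54 for Id1. Without basophil-like and monocyte-like clusters there were 191 for Nude and 2 for dKO, and without cells with shared barcodes 11 for Nude. The Nude count was 0 with the looser cell filter, with equal cells, without the thymocyte-gene clusters and in cells with Xist and no Y-linked UMI. Leaving out each WT library gave 0 to 1636, 0 to 292, 0 to 135 and 0 to 420, the lowest without WT replicate 1 and without WT replicate 2 and the highest without WT replicate 3. In cluster 4, the barcode set as a block gave 360 for Nude, no filter gave 351, 117, 551 and 168, and the DESeq2 Wald test 24 for Nude, 52 for Id1 and 26 for dKO against Id1. DESeq2 size factors gave 12 for dKO and 27 for dKO against Id1, and leaving out each WT library gave 65 to 871, 6 to 165, 174 to 1094 and 14 to 260, the lowest without WT replicate 2 and the highest without WT replicate 3.

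No share of a class had passed, nor did one with the barcode set as a block (smallest adjusted p 0.322), and 9 of 180 log2 ratios turned: NK/ILC1-like in Nude at resolution 0.5 (−2.64), basophil-like in Nude at resolution 2 (0.05), ILC2-like in dKO with centred values (2.04), ILC3-like in Id1 with T cell receptor genes kept in clustering (−1.53) and with doublets kept (−0.9). Leaving out each WT library gave −0.91 to 7.93 for basophil-like cells in Nude, −5.75 to 3.09 in dKO and −3.36 to 5.47 in Id1, each highest without WT replicate 3, which held most WT basophil-like cells, and −1.06 to 0.52 for ILC3-like cells in dKO. Tested by number, 5, 4 and 2 of the 26 clusters passed in Nude, dKO and Id1. With an estimated correlation 0 lists passed in each of the 8 comparisons of ILC2-like and all retained cells; by fry 0 passed but for 1 in dKO ILC2-like cells. Leaving out each WT library gave 11 to 17 lists for Id1 in all retained cells.

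Strain genes in all retained cells moved as follows. Tcf3 was 0.09 in Nude without the thymocyte-gene clusters, 0.17 in Id1 thinned and 0.08 without those clusters; in dKO it was −2.17 by DESeq2 (adjusted p = 1.26e-08) and −2.26 to −2.02 without each WT library (0.0286 without WT replicate 3). Tcf12 passed by DESeq2 in Nude (−1.13), dKO (−1.02) and Id1 (−0.7), with the barcode set as a block in Nude (−1.1, 0.0446), and without WT replicate 3 in Nude (0.0222; −1.16 to −1.12 over the 3) and dKO (0.0454; −1.03 to −1). Id1 transcript in Nude was 0.2 with equal cells, 0.36 thinned, 0.07 without basophil-like and monocyte-like clusters, 1.23 in cells with Xist and no Y-linked UMI and −0.62 to 3.1 without each WT library. It was −2.24 to 1.47 in dKO and 3.68 to 7.4 (0.0221 without WT replicate 3) in Id1, where the barcode set as a block gave 2.73 (0.0485).

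Single genes of ILC2-like cells turned mostly at resolution 2 and with centred values, which name other cells ILC2-like. For Nude at resolution 2 these were Cd7 (0.71), Il18r1 (0.15), Itgae (1.08) and Nrgn (−0.72), and with centred values Cd7 (0.52), Ccr6 (1.82), Klrk1 (0.92), Itgae (2.2), Itgb1 (0.61), Nrgn (−2.01), Lpcat2 (−0.37), Ccr10 (6.25), Jaml (0.36), Nebl (2.22) and Fchsd2 (0.13). In the largest cluster Cd7 (0.57), Klrk1 (0.21), Nrgn (−1.02) and Ccdc184 (−0.22) turned, with equal cells Gzma (−0.73) and in thinned cells Cd3e (4.36). Without each WT library Nude Cd3e was −2.66 to 0.36 and Trdc −1.76 to 0.42, positive without WT replicate 2. For dKO, resolution 2 turned Itga4 (−0.12), Cd247 (−0.05), Lef1 (−0.85), Junb (−0.03), Gbp2 (−1.36) and H2-Eb1 (0.28), and Ccl5 was 0.94 with centred values and 0.4 in the largest cluster. For Id1, Cd7 (0.09) and Itgae (0.43) turned at resolution 2, and Trdc (−0.33), Sox4 (−0.9), Foxp1 (−0.24), Il2ra (−0.46), Mki67 (0.34), Hmgb2 (0.04) and Slc2a3 (0.32) with centred values. Il2ra (−0.38) and Hmgb2 (0.08) turned in the largest cluster, and without each WT library Cxcr3 was −3.14 to 2.19 and Rps15 −1.24 to 0.18. For dKO against Id1, Lef1 (−0.83), Gbp2 (−1.28) and Igtp (−0.18) turned at resolution 2 and Cd74 (−0.34) in the largest cluster. Over all called genes, centred values gave the opposite direction for 22 of 73, 38 of 573, 52 of 349 and 1 of 220.

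Shares of ILC2-like cells with a T cell receptor transcript follow depth and the UMI minimum by construction. Not thinned, WT replicate 2, Nude, dKO and Id1 had Cd3d in 7.79%, 3.27%, 25.48% and 5.75% and Cd247 in 6.49%, 1.85%, 19.11% and 19.54% of cells. WT replicate 2, dKO and Id1 had Cd3e in 3.9%, 70.7% and 40.02%, and WT replicate 2, Nude and Id1 Trac in 7.79%, 2.13% and 0.88%. Trdc was in 18.18% of WT replicate 2, 3.41% of Nude, 40.76% of dKO and 45.31% of Id1 cells. In the order WT replicates 2 and 3, Nude, dKO and Id1, Cd3g was in 34.42%, 13.16%, 24.15%, 68.15% and 22.95%, Trbc in 98.05%, 93.42%, 90.06%, 92.36% and 99.71%, and Tcrg-C1 in 22.08%, 55.26%, 64.35%, 41.4% and 83.86%. With at least 2 UMIs in thinned cells, Nude, dKO and Id1 had Cd3d in 0%, 0.65% and 0.29%, Cd3e in 0%, 5.16% and 1.7% and Cd247 in 0%, 0% and 0.29%. Trac was in 0% of WT replicate 2, Nude and Id1 cells, and Trdc in 0.65% of WT replicate 2, 3.23% of dKO and 2.93% of Id1 cells. In all 5 libraries Cd3g was in 3.25%, 1.32%, 3.7%, 10.32% and 1.47%, Trbc in 37.01%, 34.21%, 33.9%, 56.13% and 64.61%, and Tcrg-C1 in 2.6%, 11.84%, 19.37%, 4.52% and 18.43%.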

Other observations

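The tests of clusters by number, the barcode set as a block and the test with cells with Xist and no Y-linked UMI were chosen only after the result was seen, and so were the clusters, genes and segments named here.

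Some clusters were nearly absent from all libraries but Nude. Cluster 21, with 1610 Nude cells, was led by Ifng, the type 1 cytokine, and the NK receptor genes Klrb1b and Klrb1f, with Cd3d in 6.2% of cells, and its share passed the edgeR test when the 26 clusters were tested by number (log2 share ratio 10.07 ± 2.03 SE, adjusted p = 0.0113). Cluster 22, 275 cells that were all Nude, was led by Cd74, H2-Eb1 and H2-Aa (10.6 ± 2.35, 0.0159), and the ILC3-like cluster 24 passed as well (6.65 ± 1.80, 0.0248), though the same cells did not in the planned test by class (6.67 ± 1.58, 0.123). Cluster 17, with 283 Nude cells of 309, was led by Nrgn and the short-chain fatty acid receptor gene Ffar2. In dKO, clusters 10 and 11 passed (6.59, 0.0242; 6.84, 0.0207), with Cd3d in 68.9% and 73.4% of cells and Gdpd3, Cd8b1 and the segment Trgv2 among their leading genes. Cluster 1, with 1422 dKO cells of 1775, was led by Gzma, the chemokine receptor gene Cx3cr1 and Gzmk. In Id1, cluster 14 passed (8.98 ± 1.91, 0.0113), with Trdc in 76.8% and Cd3d in 20.9% of cells and Igfbp4, Id1 and Ccr7, a lymph node homing receptor, among its leading genes, and so did ILC2-like cluster 6 (5.37, 0.0462). Without cells whose barcode is also in another library no cluster passed, the smallest adjusted p being 0.0694, and with the barcode set as a block none passed in Nude or Id1 (smallest 0.15). Each strain is 1 library, so strain and library cannot be separated here. A cluster's leading genes define it and are not separate results.

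Use of gamma and delta chain segments differed between libraries over all retained cells. Trgv2 took 69.6%, 71.7% and 69.96% of the UMIs of gamma variable segments in WT, 68.3% in Nude, 84.7% in dKO and 45.1% in Id1. Trdv4 took 39.8%, 61.6% and 71.8% of those of delta variable segments in WT, 63.04% in Nude, 33.3% in dKO and 91.9% in Id1. With WT libraries this far apart for Trdv4 and 1 library per strain, these shares were not tested.

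Every library held cells with Xist, the RNA of the inactive X chromosome, and cells with UMIs of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, with few cells holding both (0.67% to 3.62%). Cells with a Y-linked UMI were 27.9%, 24.2% and 25.3% in WT, 41.6% in Nude, 13.6% in dKO and 44.4% in Id1. Cells with Xist and no Y-linked UMI were 42.0%, 48.7% and 44.1% in WT, 19.8% in Nude, 38.8% in dKO and 29.2% in Id1. Some kinds of cell came nearly from 1 side. In WT replicate 2, 88.2% of cluster 12 and 87.6% of cluster 15 cells held a Y-linked UMI, while in WT replicate 3, 85.2% and 99.0% held Xist alone. The MHC class II cluster 22 of Nude held Y-linked UMIs in 70.9% and Xist alone in 1.09% of cells, and the ILC2-like cluster 18 of Nude the reverse, 8.93% and 74.1%. In dKO ILC2-like cells 2 Y-linked UMIs were counted where the rate of the library's other cells would give 43.7, and 73.3% of the cells held Xist alone.

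These values are consistent with libraries that each pool cells of both sexes, so that a kind of cell in 1 library may come mostly from a single animal; the labels give no sex. Within cells with Xist and no Y-linked UMI, 2, 33, 32 and 1 genes passed in ILC2-like cells for Nude, dKO, Id1 and dKO against Id1, from 208, 115, 501 and the 94 and 40 cells of WT replicates 2 and 3. Over the called genes measured in both, the log2 fold change there was at a median of 1.2 (Nude), 1.03 (dKO) and 1.02 times (Id1) that in all ILC2-like cells, with 2.5% of genes below 0.53, 0.76 and 0.61 times, where a difference of sex alone would take it toward 0. Their median absolute log2 fold change went from 1.61 to 1.88, 1.49 to 1.56 and 1.74 to 1.83, and their median SE from 0.32 to 0.42, 0.39 to 0.40 and 0.36 to 0.44; why the calls ended was not tested. This argues against sex as the whole source of these folds, and single animals behind a kind of cell stay open.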
